A study of Mus musculus with 35 samples.

How the data were processed

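The data are single-cell RNA counts of 35 mouse embryonic fibroblasts, 21 with micronuclei and 14 without, taken 48 h after a dose of 1 Gy; cells were moved to membrane dishes 32 h after the dose and captured by laser. The deposited table holds whole-number read counts, not normalized, for 19147 features, of which 19085 are genes and 62 are ERCC spike-in RNAs. Reads were aligned with STAR to GRCm38.p5 and counted per gene with Rsubread, and cells were filtered with scater on ERCC share (at most 10%), genes (at least 2000) and counts (at least 40000), per the submitters' processing notes; versions and whether strand was used in counting are not given in the sources used here. Reads of overlapping genes on opposite strands can therefore not be told apart, which makes the counts of Eif2ak2, Ifi35, Irf3, Irf7, Cxcl10, Atr, Sun1, Cdkn1a, Dusp1, Sqstm1, Igfbp7, Hexa and Thbs1 uncertain too, among others named with an overlap in the report. No read was counted in these cells for 827 of the gene entries. All 35 cells were used and no further filter on cells was applied; a doublet caller was not run on 35 hand-picked cells. The cells' ERCC shares reached 7.39%, and their lowest numbers were 2391 genes and 56766 reads. Spike-ins stayed out of totals and ratios. The deposited phenotype table repeats the record fields of each cell and names no culture, embryo, plate or date, so batches could not be compared. All 595 pairs of cells were compared and 0 were identical; their correlation of log2 CPM across genes, which are not independent replicates, ranged from 0.412 to 0.755. The number of unused columns of other samples was 0.

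Each cell is its own library and no replicate culture is named, so each group was treated as 1 sample. Reads were summed over the cells of a group, 11084425 with micronuclei and 11612303 without, and expressed as CPM (the usual scaling of reads on genes to a common total, spike-ins left out). The log2 ratio is log2((CPM with micronuclei + 1)/(CPM without + 1)). A gene was measured with at least 5 CPM over all cells and at least 5 reads in 5 cells, which 8390 genes were. Deep cells weigh more in a sum, so an equal-weight ratio of mean CPM per cell and the ratio without each of the 35 cells are given beside it. The 95% Poisson and Clopper-Pearson intervals cover counting error only, since reads without molecular identifiers are not independent molecules. A count of 0 was set to a floor of 3 reads over the group for a fold. The median of a gene list was placed among 10000 random lists of the same size drawn from 20 bins of expression; percentiles describe these libraries, ignore that genes of a list vary together, and are no test. Thinning drew 119337 reads without replacement from each of 30 cells; 4 micronucleated cells and 1 other were too shallow and left out. The symbols of 18218 gene entries were found in a reference list of gene names. Gene coordinates come from GENCODE annotation of GRCm38, matched by symbol for the named genes. Cyr61 and Mb21d1 had no match there, so no position is given for them. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used, with R 4.3.3, edgeR 4.0.16 for TMM factors (1.05 and 0.952) and scran 1.30.0 for size factors per cell.

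The following choices were made before the data were examined. Lists covered interferon-stimulated genes, antigen presentation, cytosolic DNA sensing, NF-κB targets, senescence and secretory genes, p53 targets, DNA damage repair, S phase, G2M phase, nuclear envelope and repair, autophagy and lysosome, extracellular matrix, contractile and YAP genes, glycolysis and hypoxia, unfolded protein and integrated stress, immediate early and heat shock genes, nuclear oxidative phosphorylation, mitochondrially encoded, ribosomal protein and sex-linked genes, and markers of macrophage, endothelial, epithelial, neural, skeletal muscle, adipocyte, chondrocyte and erythroid cells. Genes are named by rule: of genes with at least 20 CPM in either group and at least 5 reads in 50% of the cells of the group where they were higher, the 12 higher and 12 lower with the largest smallest log2 ratio of the same sign over summed counts, equal weights and every leave-out; in each list up to 4 measured members by the same value; and always Cgas, Sting1, Ifnb1, Cxcl10, Ccl5, Ifit1, Ifit3, Isg15, Oasl2, Irf7, Cdkn1a and Mdm2; a further gene of this set is not reported here. Markers of cell types and the fibroblast genes Col1a1 and Vim serve to describe the cells. Alternatives were equal weights, mean log2 CPM, TMM and scran scaling, 0.1 or 5 CPM added, no filter or a stricter filter (20 CPM and 10 cells), thinning, other read minimums (1 or 10), and leaving out each cell. Alternatives added after seeing the data were leaving out 6 cells with under 4000 genes or over 9% mitochondrial reads, cells with 5000 to 8000 genes after thinning, leaving out 4 cells with macrophage markers, and totals without mitochondrial reads. The range of 5000 to 8000 genes does not match the groups: in it micronucleated cells reached 7958 genes and the others 6630.

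The procedure was tested on simulated data: counts for 19085 genes were drawn from the real groups' means and cell totals with 200 genes changed. True folds of 2, 4 and 8 gave median log2 ratios of 1.29, 1.97 and 3.08, with the right direction in 90.1%, 97.0% and 98.4% of genes and, with any cell left out, in 78.9%, 87.9% and 96.8%. Of the 24 genes the rule named in that set 21 were truly changed. Of 200 unchanged lists 9.5% fell outside the central 95%, so a percentile near its edge is weak evidence. With no gene changed, in 20 draws, the leading higher gene still had a median ratio of 2.77 and the leading lower gene −3.15.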

Results

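Transcriptomes of 35 individual mouse embryonic fibroblasts (MEFs, connective tissue cells cultured from C57Bl/6J embryos and grown at 3% oxygen) were compared 48 h after 1 Gy of ionising radiation. DNA was stained with PicoGreen, each cell was cut out by laser, and its polyadenylated RNA was copied by Smart-seq2, a full-length method whose reads carry no molecular identifiers. Of these cells 21 held micronuclei, small membrane-bound bodies of chromatin outside the main nucleus, and 14 held none. Reads counted on genes numbered 57514 to 1794113 per micronucleated cell (median 281800) and 56766 to 2023111 per cell without micronuclei (median 736715). Each library is 1 cell and no culture, embryo or animal is named, so each group counts as 1 sample: the values below describe these cells, with no p-value and no replicate check. The 95% intervals (exact Poisson for summed reads, exact Clopper-Pearson for shares of cells) cover counting error only.

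Micronucleated cells had a median of 6812 genes with at least 1 read (SD 1794.3, range 2391 to 8964), against 6082 (SD 1571.8, range 3861 to 8229) in cells without micronuclei. The difference of 730 genes was smaller than the SD of either group, although 5 micronucleated cells lay above the highest cell of the other group. After every cell was thinned to 119337 reads, which left 17 and 13 cells, the medians were 5825 and 5285 genes, and 7 micronucleated cells lay above the highest other cell. The share of reads on mitochondrial transcripts had a median of 1.43% and 2.31%; it reached 25.7% in micronucleated cell 18 and at most 3.81% in cells without micronuclei. Fibroblast transcripts were abundant in both groups: Col1a1, a chain of type I collagen, stood at 2489.0 and 2615.7 CPM (reads scaled to a common total of the summed group) and the intermediate filament gene Vim at 2027.3 and 2588.3 CPM. Over the 8390 measured genes the median log2 ratio of micronucleated over other cells was 0.15, and 0.05 when every cell had equal weight. Ratios of lists are therefore set against random lists of the same expression.

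**Figure D1:**
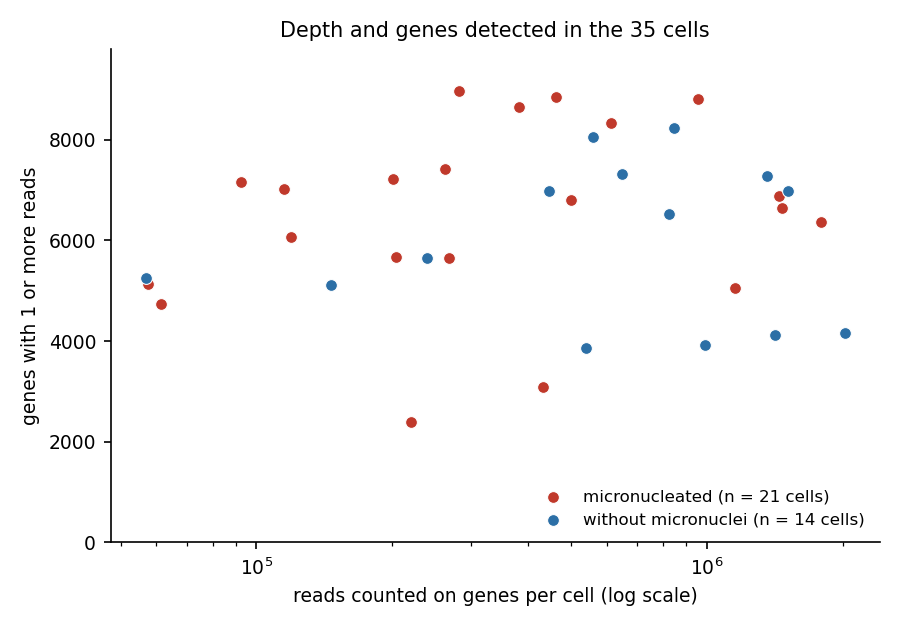
Reads counted on genes per cell (x axis, log scale) and genes with at least 1 read (y axis, number) for 21 micronucleated cells and 14 cells without micronuclei, 1 point per cell. Micronucleated cells reached 8964 genes and the others 8229, with overlapping ranges of depth.

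Whether a micronucleus is accompanied by transcripts of the innate immune response, which the cytosolic DNA sensor cGAS can start, is the question the comparison addresses. In summed reads, interferon-stimulated genes went in both directions. Trim25, a ubiquitin ligase of antiviral RNA sensing, was higher in micronucleated cells at 25.4 CPM (22.6 to 28.6) against 3.70 (2.68 to 4.99), a log2 ratio of 2.49, with at least 5 reads in 7 of 21 and 2 of 14 cells. Ifit2, an antiviral protein that binds RNA, stood at 38.3 against 1.90 CPM (log2 ratio 3.76), but 72.7% of its reads came from micronucleated cell 14, without which the log2 ratio was 1.98. Ifi35 was higher at 35.8 against 12.8 CPM (log2 ratio 1.41, 12 of 21 and 4 of 14 cells). Its log2 ratio was 0.76 without micronucleated cell 11 and 3.13 without cell 11 of the other group. It was −0.00048 among 21 cells in a set range of genes detected, 5000 to 8000 after thinning. This range does not make the groups equal in genes detected. Without cell 10 of the group without micronuclei Trim25 was at 3.41 and Ifit2 at 4.94. Eif2ak2, which encodes the RNA-activated kinase PKR, was lower in summed reads at 36.7 CPM (33.2 to 40.5) against 144.2 (137.4 to 151.3). Its log2 ratio was −1.95, and −2.63 without micronucleated cell 13. The share of cells did not go that way, with at least 5 reads of Eif2ak2 in 8 of 21 and 5 of 14 cells. Its median per cell was 9.44 CPM in micronucleated cells and 0 in the others.

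Of 55 listed interferon-stimulated genes, 41 had reads, 14 were not analysed here, and 11 were measured, that is reached a summed 5 CPM and 5 reads in at least 5 cells. Among the 11, 6 were higher and 5 lower in micronucleated cells; 5 and 1 of them kept their sign when cells had equal weight and whichever cell was left out. The list median log2 ratio was 0.96, at percentile 95 of 10000 random lists, inside their central 95%. With equal weight for every cell it was 0.03, at percentile 37.7. With scran size factors it was −0.062. It lay outside the central 95% in 3 of 14 settings: 1.00 at percentile 99.0 after thinning, when 7 of the genes were measured, 0.62 at percentile 99.7 over all 41 genes with reads, and 1.28 at percentile 99.1 without the 4 cells with macrophage markers. Without micronucleated cell 7 the list median was −0.11 at percentile 20.5; without cell 12 of the other group the list median was 1.38 at percentile 99.1. Per cell, the CPM summed over the measured list had a median of 889 (SD 400.4) and 834 (SD 339.5); 67.5% of the reads of this list were of Ifitm3, an abundant membrane protein gene named after its values were seen. Over all 41 genes with reads the sum had a median of 1062.3 (SD 421.5) and 841.1 (SD 339.9), a difference below either SD, with 5 micronucleated cells above the highest other cell. The number of listed genes with at least 5 reads had a median of 6 (SD 3.81, range 1 to 14) in micronucleated cells and 4 (SD 2.41, range 1 to 9) in the others, a difference below the SD in micronucleated cells. At equal depth the medians were 4 and 3, and 4 micronucleated cells lay above the highest other cell.

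Several interferon targets that were fixed for report were near the detection limit. Isg15, a ubiquitin-like modifier, had 55 reads in micronucleated cells, 44 of them in cell 13, and 0 in the others, at least 19.2-fold higher against a floor of 3 reads over the group (0.258 CPM). That bound rests on cell 13, without which the log2 ratio of Isg15 was 1.13 in place of 2.58. The chemokine gene Ccl5 had 66 reads, all in micronucleated cell 15, and 0 in cells without micronuclei. Against the same floor the summed fold was at least 23.1, which covers counting error only. It rests on that 1 cell, without which the log2 ratio of Ccl5 was 0 in place of 2.80. Cxcl10 had 4 reads and Irf7 1 read, both in micronucleated cell 18, against 0. Neither gene reached 5 reads in any cell, so no difference in the share of cells was detectable at this depth. Ifnb1, Ifit1, Ifit3 and Oasl2 were not analysed here. Mb21d1, the symbol used for cGAS in the deposited table, stood at 1.44 CPM (0.825 to 2.34) in micronucleated cells and 31.9 CPM (28.7 to 35.3) in the others, with at least 5 reads in 1 of 21 and 3 of 14 cells. Of its reads 80.3% came from cell 7 without micronuclei. Without that cell the log2 ratio was −1.57, and without micronucleated cell 10 −4.67. With equal weight for every cell it was −1.78, and as little as −0.086 when a cell was left out. After thinning 0 of 17 and 1 of 13 cells had at least 5 reads of Mb21d1, which did not reach the minimum for a measured gene. Tmem173, the adaptor STING, was at 30.2 against 18.2 CPM, and its sign depended on the cell left out (log2 ratio −0.16 to 2.52).

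**Figure D2:**
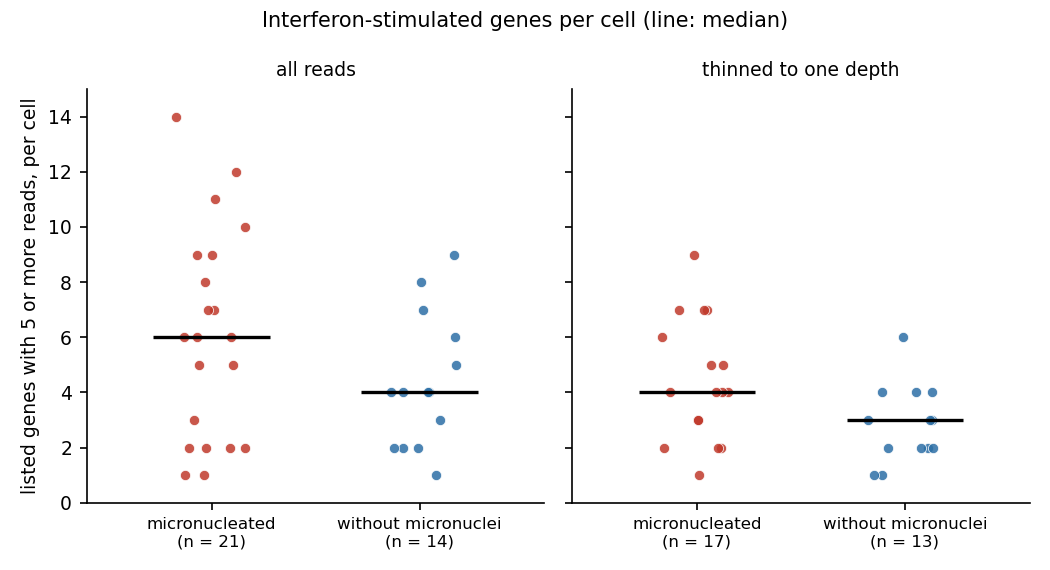
Number of listed interferon-stimulated genes with at least 5 reads in each cell (y axis, number of genes), by group, with all reads (left, 21 and 14 cells) and after thinning to 119337 reads (right, 17 and 13 cells); each point is 1 cell and each line a median. Medians were 6 and 4 with all reads and 4 and 3 after thinning, with overlapping ranges.

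Genes of the neighbouring pathways differed without a common direction. In antigen presentation 6 of 8 measured genes were higher and 2 lower: the class I heavy chain gene H2-D1 stood at 229.0 against 61.7 CPM (log2 ratio 1.87, and 1.26 without micronucleated cell 13), while the chaperone gene Canx was lower at 1291.5 against 3280.1 CPM (log2 ratio −1.34). The median of 0.45 lay at percentile 93.3. In cytosolic DNA sensing 9 of 13 were higher, led by Mavs, the mitochondrial adaptor of RNA sensing (17.9 against 2.15 CPM, log2 ratio 2.58, 60.5% of reads in micronucleated cell 9, 1.195 without it and 3.69 without cell 10 of the other group), and Irf3 (log2 ratio 1.43, 0.77 without micronucleated cell 7 and 0.41 with equal weight). That median was 0.44 at percentile 66.6, −0.19 after thinning and −0.038 among the cells in the set range of genes detected. Targets of NF-κB were lower in 9 of 13, among them the chemokine gene Ccl7 (180.3 against 484.8 CPM, log2 ratio −1.42, and −2.04 without micronucleated cell 14) and Sod2, mitochondrial superoxide dismutase (55.8 against 192.8 CPM, log2 ratio −1.77). Their median of −0.45 lay at percentile 2.31 and was −0.14 at percentile 22.7 with equal weight; it moved inside the central 95% in 17 of 35 leave-outs, to −0.15 without cell 8 of the group without micronuclei. As the mean over cells of log2 CPM the NF-κB median was 0.29.

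The p53 targets, which arrest or kill cells after DNA damage, were 13 higher and 14 lower of 27, with a median log2 ratio of −0.0013 at percentile 30.6 and 0.37 in mean log2 CPM. Cdkn1a, the cell cycle inhibitor p21, had at least 5 reads in all 35 cells and stood at 1605.7 CPM (1582.2 to 1629.4) against 1477.7 (1455.7 to 1500.0), with a sign that depended on the cell left out. Mdm2, the ligase that degrades p53, was lower at 129.0 against 226.0 CPM (log2 ratio −0.80), whereas the detoxifying enzyme gene Ephx1 (log2 ratio 2.20, and 3.01 without cell 4 of the group without micronuclei) and the death gene Bax (0.56) were higher. In the senescence and secretory list 5 were higher and 5 lower (median −0.07, percentile 34.3); the protease gene Plau was higher (log2 ratio 2.12, 1.49 without micronucleated cell 9 and 2.81 without cell 5 of the other group) and Igfbp7 lower (−0.59). Plau had at least 5 reads in fewer micronucleated cells, 6 of 21 against 7 of 14, and its difference in mean log2 CPM was −0.06. Repair genes were 8 higher and 9 lower (median −0.06, percentile 15.1, and 0.20 after thinning): Atr, a kinase of the replication stress checkpoint, was at 39.5 CPM (35.9 to 43.4) against 1.55 (0.919 to 2.45), with at least 5 reads in 9 of 21 and 1 of 14 cells, and Brca1 was at 1.62 against 23.9 CPM, with 55.4% of its reads in cell 7 without micronuclei. Nuclear envelope genes were 9 higher and 11 lower (median −0.02, percentile 26.9, and 0.44 in mean log2 CPM), with Chmp7, a membrane-sealing subunit of ESCRT-III (log2 ratio 2.48), and the linker gene Sun1 (2.17, 0.96 with equal weight and 3.02 without cell 11 of the group without micronuclei) higher and the pore gene Nup153 lower (−1.52, but 0.25 in mean log2 CPM). Without micronucleated cell 11, which held 56.5% of its reads, Chmp7 was at 1.11; without cell 7 of the other group Nup153 was at −0.51 and Brca1 at −2.30.

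Contractile genes and targets of the mechanosensitive regulator YAP were higher in micronucleated cells as a group. Of 16 measured, 12 were higher and 4 lower, and 10 and 2 kept their sign with equal weight and any cell left out. Cyr61, a secreted matrix protein and YAP target, stood at 2523.0 CPM (2493.5 to 2552.7) against 1010.0 (991.8 to 1028.4), a log2 ratio of 1.32. The smooth muscle actin gene Actg2 was at 319.4 against 149.0 CPM (log2 ratio 1.10), Ankrd1 at 217.3 against 106.5 CPM (1.02) and Amotl2 at 197.8 against 103.9 CPM (0.92). The list median was 0.62 at percentile 99.98. It was 0.38 at percentile 99.97 with equal weight. Among 21 cells in the set range of genes detected after thinning it was 0.30 at percentile 99.6. In that range micronucleated cells reached 7958 genes and the others 6630, so the difference in genes detected was not removed. Per cell the summed CPM of the list had a median of 16192.4 (SD 7349.1) and 13046.3 (SD 7795.2), a difference below the spread between cells.

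Immediate early genes, induced within minutes of a stimulus, went both ways, with larger ratios among the higher ones. Ier2 stood at 157.2 against 29.9 CPM, a log2 ratio of 2.36, with at least 5 reads in 17 of 21 and 9 of 14 cells. The phosphatase gene Dusp1 was at 150.2 against 22.4 CPM (log2 ratio 2.69, and 3.40 without cell 13 of the other group). Fos was at 133.5 against 27.7 CPM (2.23), with 58.9% of its reads in micronucleated cell 14, without which the log2 ratio was 0.63; without cell 4 of the other group it was 3.55. The inducible chaperone gene Hspa1b, which shares sequence with Hspa1a, went the other way (16.4 against 87.8 CPM, −2.35), as did the immediate early genes Fosb (−1.99), Zfp36 (−1.17) and Klf2 (−0.65), named after their values were seen. With heat shock genes included, 10 of 18 were higher and 8 lower, against 56.0% higher of all measured genes, with a median of 0.57 at percentile 98.5. The median was 0.35 at percentile 98.2 with equal weight. It stayed above 0 but moved inside the central 95% without micronucleated cells 1, 11 or 13 or without cells 5, 10 or 11 of the other group, at the least to 0.39 at percentile 95.1 without micronucleated cell 13; it lay outside in 9 of 14 settings.

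Replication genes were lower in summed reads of micronucleated cells. Of 36 measured S phase genes 25 were lower and 11 higher, and 8 and 1 kept their sign with equal weight and any cell left out. Mcm2, a subunit of the replicative helicase, stood at 10.8 CPM (8.98 to 12.95) against 59.0 (54.7 to 63.6), a log2 ratio of −2.34, with at least 5 reads in 7 of 21 and 8 of 14 cells. Atad2 was at 78.0 against 256.1 CPM (−1.70), the histone chaperone gene Nasp at 32.1 against 65.7 CPM (−1.01, and −1.60 without micronucleated cell 21), and Uhrf1, which maintains DNA methylation, at 9.65 against 91.9 CPM (−3.12). Of the reads of Uhrf1 73.8% came from cell 7 without micronuclei, and without it the log2 ratio was −1.04; that of Atad2 was then −0.88. Among the cells in the set range of genes detected Uhrf1 was at 0.051. The list median was −0.38 at percentile 0.71, and −0.32 at percentile 1.03 with equal weight. Without cell 4 of the group without micronuclei it was 0.14 at percentile 33.0; it also moved inside the central 95% without micronucleated cells 7 (−0.21), 11 (−0.26) or 14 (−0.22), and was −0.74 without micronucleated cell 9. Per cell the summed CPM of the list had a median of 1397.4 (SD 1365.1) and 2413.5 (SD 1381.8), a difference below either SD. At equal depth the number of S phase genes with at least 5 reads had a median of 11 in micronucleated cells and 10 in the others.

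Mitotic genes went both ways, 26 higher and 23 lower of 49, with a median of 0.06 at percentile 29.2 and −0.17 after thinning. Ccnb2, a mitotic cyclin, was at 34.1 against 1.64 CPM (log2 ratio 3.74; 65.5% of reads in micronucleated cell 13, 2.38 without it and 5.13 without cell 3 of the other group), the checkpoint kinase gene Bub1 at 12.1 against 1.03 CPM (2.69; 2.06 without micronucleated cell 9 and 3.47 without cell 13 of the other group), and Anln, a scaffold of the cleavage furrow, at 70.7 against 12.1 CPM (2.46). Anln was at 1.44 with equal weight and had at least 5 reads in 10 of 21 and 9 of 14 cells. The list median moved to 0.94 at percentile 99.97 without cell 4 of the group without micronuclei and to −0.37 at percentile 0.71 without micronucleated cell 9.

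Transcripts encoded in mitochondrial DNA were lower in summed reads in 7 of 8 measured genes. Among them was mt-Nd2 of respiratory complex I at 575.1 against 1248.8 CPM (log2 ratio −1.12, but 0.047 in the set range of genes detected). Their median was −0.56 at percentile 0.04, and −0.05 at percentile 37.3 when each cell had equal weight; the share of mitochondrial reads differed widely between cells, as given above. Nuclear genes of oxidative phosphorylation had 9 higher and 12 lower (median −0.13, percentile 24), with Uqcrc1 of complex III higher (594.7 against 244.9 CPM, 1.28). Ribosomal protein genes had a median of −0.08 at percentile 43.9 and 0.08 at percentile 86.1 with equal weight; Rps14 was lower (−0.41) and Rpl5 higher (0.24). Glycolytic and hypoxia genes were higher in 16 of 21 (median 0.17, percentile 76.0), with the phosphofructokinase gene Pfkl at 106.6 against 26.8 CPM (1.95, and 3.09 without cell 1 of the group without micronuclei).

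Autophagy and lysosome genes were higher in 14 of 21, among them the receptor gene Sqstm1 (511.1 against 278.5 CPM, 0.87) and Hexa (0.90). Their median of 0.30 lay at percentile 91.1, and without micronucleated cell 13 it was 0.45 at percentile 98.4. Without cell 7 of the group without micronuclei it was 0.14, and the lowest percentile of the leave-outs was 75.8, without micronucleated cell 21. Stress genes of the unfolded protein and integrated stress responses were 7 higher and 8 lower (median −0.10, percentile 35.2; 0.19 with equal weight; 0.50 at percentile 98.7 without cell 10 of the group without micronuclei): the regulator gene Atf4 (208.9 against 98.3 CPM, 1.08) and its target Asns (249.6 against 90.8 CPM, 1.45, and 0.64 with equal weight) were higher, and the chaperone gene Dnajb9 was lower (−1.11, and −0.42 without cell 7 of the group without micronuclei). Extracellular matrix genes were lower in 14 of 20, while Thbs2 was higher (1.51). Thbs1 was at 4627.6 against 7464.3 CPM (−0.69, but 0.040 among the cells in the set range of genes detected). The cross-linking enzyme gene Loxl1 was at 185.0 against 409.7 CPM (−1.14). The list median was −0.23 at percentile 7.34, −0.27 at percentile 1.08 with equal weight and −0.40 at percentile 0.49 with scran size factors. It was 0.17 among the cells in the set range of genes detected. Without micronucleated cell 13 it was −0.37 at percentile 0.79, and without cell 7 of the group without micronuclei 0.05.

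**Figure D3:**
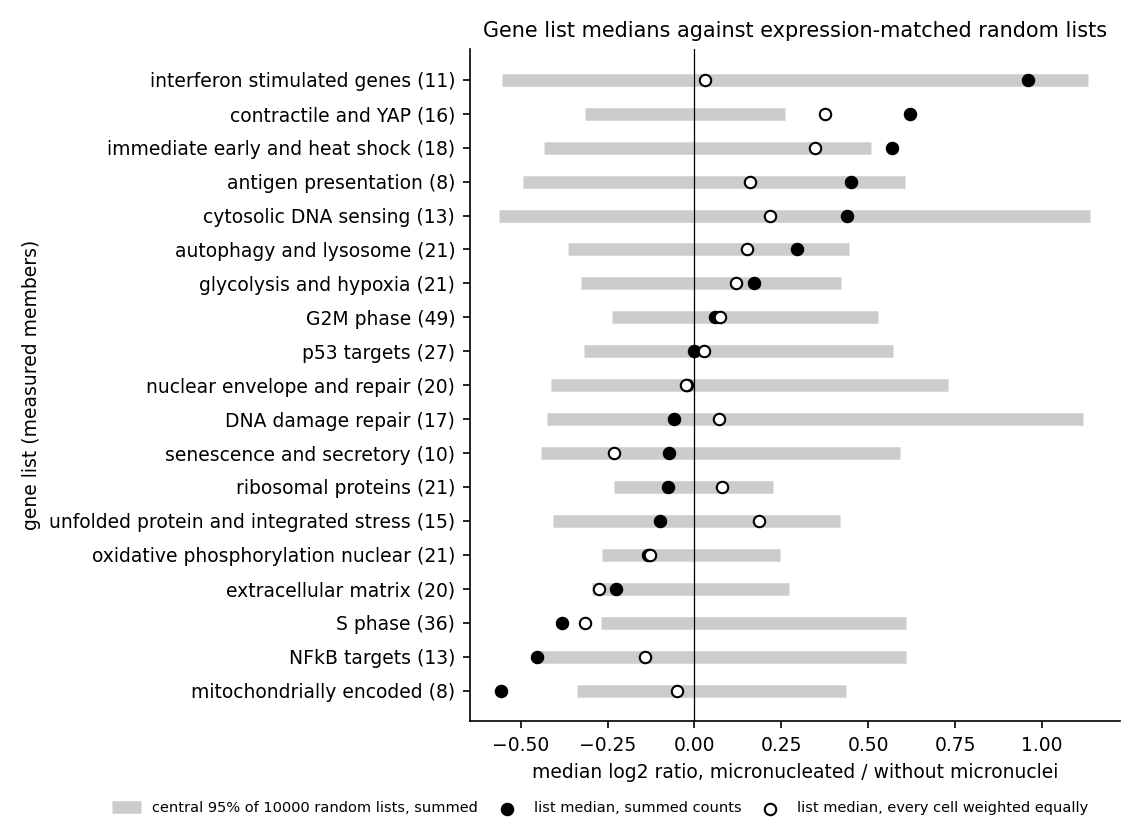
Median log2 ratio of summed CPM, micronucleated over other cells (x axis), for 19 gene lists (y axis, measured members in brackets); filled points are summed counts, open points give every cell equal weight, and grey bars are the central 95% of 10000 expression-matched random lists of summed counts. Filled points lie outside the bars for contractile and YAP genes (0.62), immediate early and heat shock genes (0.57), S phase (−0.38), NF-κB targets (−0.45) and mitochondrially encoded genes (−0.56).

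Among 4167 genes with at least 20 CPM in either group and at least 5 reads in 50% of the cells of the group where they were higher, the leading genes were 12 higher and 12 lower, ranked by the ratio that remained when cells had equal weight and any cell was left out. Sharpin, a subunit of the linear ubiquitin ligase complex, led the higher genes at 63.9 CPM (59.3 to 68.8) against 0.861 (0.413 to 1.58), a log2 ratio of 5.12, with at least 5 reads in 13 of 21 cells (61.9%, 38.4 to 81.9) and 1 of 14 (7.14%, 0.181 to 33.9). It lies on the minus strand of chromosome 15, 76347040 to 76351111 (GRCm38). Mad2l1bp, which silences the spindle checkpoint (chromosome 17, 46147387 to 46153553, minus strand), was at 34.2 CPM (30.8 to 37.8) against 0.947 (0.473 to 1.70), a log2 ratio of 4.18, in 11 and 1 cells. Gpx3, a secreted glutathione peroxidase (chromosome 11, 54902453 to 54910377, plus strand), was at 121.7 CPM (115.3 to 128.4) against 7.41 (5.92 to 9.15), a log2 ratio of 3.87, in 14 and 4 cells. The splicing factor gene Sart1 (3.51), the endosomal gene Plekhf1 (187.2 against 13.5 CPM, 3.70), Npdc1 (3.23), Mthfsd (3.33), the methyltransferase gene Smyd2 (2.71), Gnl1 (3.20), the actin regulator gene Flii (2.67), Zc2hc1a (2.58) and Qpctl (2.87) followed. A single cell held 52.4% of the reads of Sharpin; its log2 ratio ranged from 4.21 to 5.67 over the leave-outs. Leaving out a single cell moved the fold of 15 of the 24 leading genes by more than 1.5 times without a change of sign: Gpx3 moved to 3.16 without micronucleated cell 13 and 4.60 without cell 5 of the other group, Mthfsd to 2.60 without micronucleated cell 11, and Mthfsd to 6.14 and Qpctl to 5.54 without cell 11 of the other group. Away from 0, Mad2l1bp moved to 4.78, Plekhf1 to 4.86, Gnl1 to 3.88 and Zc2hc1a to 3.96 without cells 10, 6, 5 and 4 of that group.

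Among the lower genes, Ccdc71 (chromosome 9, 108460527 to 108465938, plus strand) stood at 6.23 CPM (4.84 to 7.88) against 85.4 (80.2 to 90.9), a log2 ratio of −3.58, in 4 of 21 and 7 of 14 cells. Sema3e, a secreted guidance cue (chromosome 5, 14025276 to 14256689, plus strand), was at 22.2 CPM (19.5 to 25.2) against 230.1 (221.5 to 239.0), a log2 ratio of −3.32, in 11 and 10 cells. Alyref, an mRNA export adaptor (chromosome 11, 120592121 to 120598365, minus strand), was at 13.3 CPM (11.2 to 15.6) against 62.4 (58.0 to 67.2), a log2 ratio of −2.15, in 9 of 21 (42.9%) and 13 of 14 cells (92.9%). The exocyst gene Exoc1 (−3.12), the tryptophanyl-tRNA synthetase gene Wars (28.9 against 154.4 CPM, −2.38), Tmem129 (−3.44), Hspa1b (−2.35), Ttc28 (−2.12), Plagl2 (−3.01), the mitophagy receptor gene Fundc1 (−2.78), Ago3 (−3.27) and the RNA polymerase III gene Polr3g (−2.86) were also lower. Cell 7 without micronuclei held 51.9% of the reads of Fundc1 and 50.5% of those of Ago3, whose log2 ratios without it were −1.79 and −2.38. Leaving out cells 5, 8 and 4 of that group moved Ccdc71 to −2.83 (−2.96 without cell 1), Exoc1 to −2.22 and Tmem129 to −2.72. Without micronucleated cell 14 Wars was at −3.52 and Fundc1 at −4.51, and without micronucleated cells 10, 13 and 9 Ccdc71 was at −4.85, Exoc1 at −3.79 and Hspa1b at −3.18. Exons of Npdc1 overlap those of Entpd2 on the same strand; those of Gnl1, Flii, Qpctl, Ccdc71 and Tmem129 overlap a protein-coding gene on the other strand and those of Sart1 and Smyd2 another annotated gene there, so their counts are uncertain. Among the 21 cells in the set range of genes detected, the median log2 ratio of the 12 higher genes was 2.31. That of the 12 lower genes was −1.66.

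**Figure D4:**
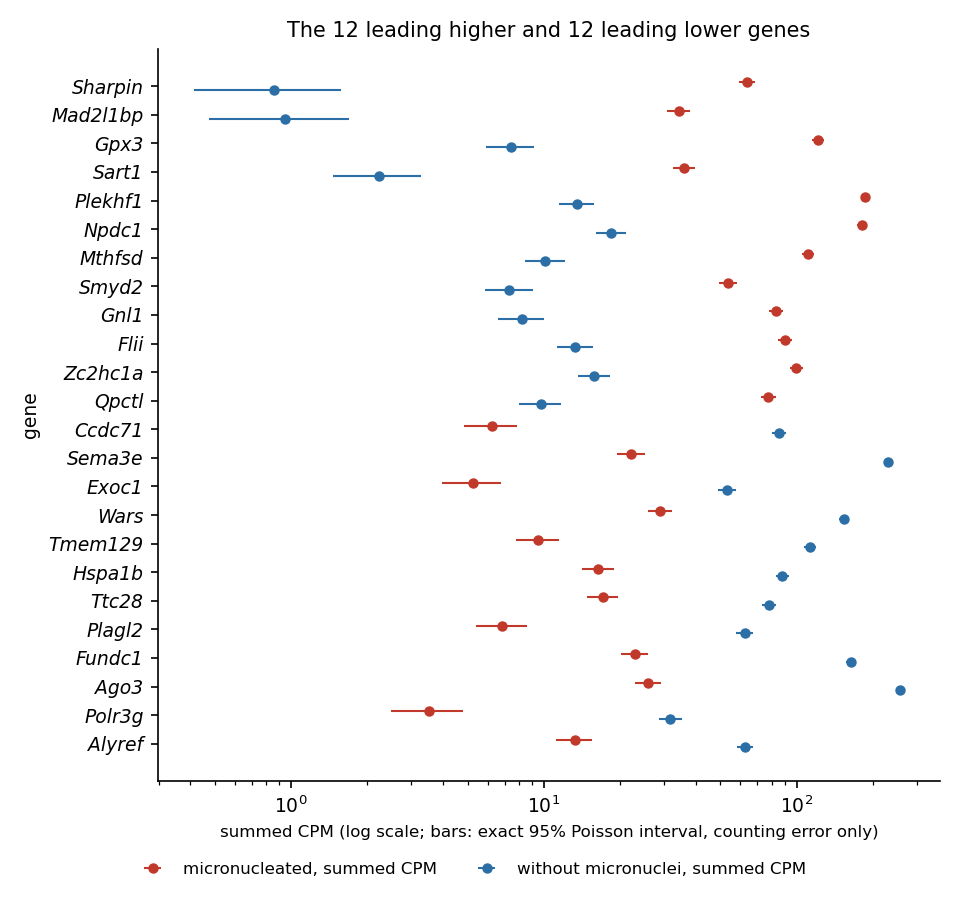
Summed CPM (x axis, log scale) of the 12 leading higher and 12 leading lower genes (y axis) in micronucleated cells (red) and cells without micronuclei (blue), with exact 95% Poisson intervals for counting error only. The widest separation is that of Sharpin, at 63.9 and 0.861 CPM.

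Markers of macrophages were found in micronucleated cells. Lyz2 (lysozyme) stood at 775.4 CPM against 0, and Csf1r, the receptor of a macrophage growth factor, at 33.5 CPM against 0. Micronucleated cell 10 held at least 5 reads of all 8 markers, 9508 reads in all, of which 8530 were of Lyz2, 463 of Tyrobp and 237 of Fcer1g. The next highest cell, micronucleated cell 6, held 320, all of Csf1r. Cd68, a lysosomal protein abundant in macrophages, stood at 17.6 and 18.7 CPM and did not separate the groups. All 4 cells with at least 5 reads of 2 or more macrophage markers were micronucleated, but apart from cell 10 they reached that minimum with few reads. Cell 1 held 6 of Csf1r and 7 of Cd14, cell 4 held 21 of Lyz2 and 5 of Tyrobp, and cell 18 held 40 of Lyz2 and 5 of Cd68. Without the 4 cells the list median log2 ratio was 1.28 for interferon-stimulated genes at percentile 99.1, 0.67 for contractile and YAP genes, 0.50 at percentile 96.9 for immediate early and heat shock genes, and −0.35 at percentile 2.04 for S phase. Cell 10 also held the only reads of the interferon-stimulated genes Oas2 (59), Rtp4 (19) and Oas1a (12), genes named after their values were seen; without this cell the interferon-stimulated list median was 1.03 at percentile 96.3.

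**Figure D5:**
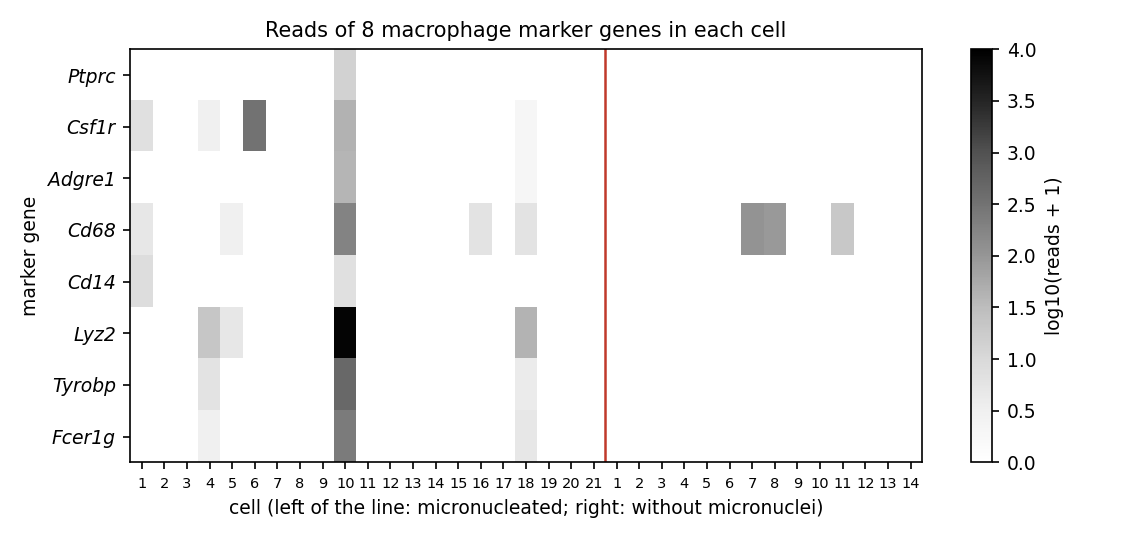
Reads of 8 macrophage marker genes (y axis) in each of the 35 cells (x axis, micronucleated cells 1 to 21 left of the line and cells 1 to 14 without micronuclei right of it), as log10 of reads plus 1. Micronucleated cell 10 has reads of all 8 genes, with 8530 of Lyz2.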

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

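The tests with 6 cells left out and with cells in the set range of genes detected were chosen after the data were seen. So were those without macrophage-marker cells and without mitochondrial reads in the totals. The others were planned. Over 19 lists, 228 of 284 medians under an alternative moved by less than the spread of random lists, 54 moved by more, and 2 medians of lists outside the central 95% took the other sign (NF-κB targets and S phase). Of the 284, 45 had another sign than the summed median, in 13 lists. Of 106 named genes, 100 kept their sign in every leave-out and 88 in all settings compared; leaving out 1 cell moved the fold of 53 of them by more than 1.5 times; the cause of each shift was not tested unless stated. The median of all genes was 0.15 for summed counts, 0.05 with equal weight, 0.30 as mean log2 CPM, 0.01 with TMM and 0.00 with scran, so medians shift with the scale. Contractile and YAP genes stayed outside the central 95% of random lists in 14 of 14 settings and S phase genes in 13; immediate early and heat shock genes did so in 9, mitochondrially encoded genes in 10 of 13, NF-κB targets in 7, interferon-stimulated genes in 3, extracellular matrix genes in 2, ribosomal genes in 1 and the other lists in 0. With equal weight for every cell, medians were 0.030 for interferon-stimulated genes, 0.16 for antigen presentation, −0.14 for NF-κB targets, 0.38 for contractile genes, 0.19 for the stress list, −0.049 for mitochondrially encoded genes and 0.078 for ribosomal genes. As mean log2 CPM they were 0.20 for interferon-stimulated genes, 0.29 for NF-κB targets, 0.37 for p53 targets, −0.14 for S phase, 0.44 for the nuclear envelope, 0.41 for contractile and 0.20 for stress genes, with Plau at −0.058 and Nup153 at 0.25. TMM gave −0.27 for nuclear oxidative phosphorylation and −0.22 for ribosomal genes. With scran they were −0.062 for interferon-stimulated genes, 0.054 for antigen presentation, −0.40 for extracellular matrix, 0.33 for contractile, 0.29 for immediate early and −5.2e-07 for mitochondrially encoded genes. Without the filter NF-κB targets were at −0.034 and mitochondrially encoded genes at −0.30, and with the stricter filter stress genes were at 0.22. After thinning DNA sensing was at −0.19, NF-κB at −0.13, G2M at −0.17, contractile at 0.41 and stress genes at 0.37. In 21 cells in the set range of genes detected (13 and 8), medians were 0.44 for interferon-stimulated genes and −0.038 for DNA sensing. They were −0.058 for NF-κB, −0.29 for p53 targets, 0.17 for extracellular matrix and 0.30 for contractile genes. Stress genes were at 0.17 and ribosomal genes at −0.25. There Ifi35 (−0.00048), Rnaseh2c (−0.038), Jak1 (0.48), Uhrf1 (0.051), Tor1a (−0.46), Thbs1 (0.040), mt-Nd2 (0.047), mt-Nd6 (0.023) and Rpl8 (−0.034) changed sign. Without 6 cells, 4 of them micronucleated, Jak1 was at 0.33 and Igfbp4 at 0.53. Leaving out each cell in turn gave −0.11 to 1.38 for interferon-stimulated genes, −0.63 to −0.15 for NF-κB, −0.25 to 0.24 for p53 targets, −0.49 to 0.33 for repair, −0.74 to 0.14 for S phase, −0.37 to 0.94 for G2M, −0.27 to 0.42 for the nuclear envelope, −0.37 to 0.048 for extracellular matrix, 0.42 to 0.82 for contractile, 0.023 to 0.37 for glycolysis and −0.38 to 0.50 for stress genes. Shares of cells with a named gene stayed within their interval in 564 of 636 values; 31 moved at a minimum of 1 read, 8 at 10 reads and 33 after thinning, which removes reads by design. The differences in genes per cell and in interferon-stimulated genes and reads per cell moved by less than the SD between cells in the alternatives run. The difference in total reads per cell was recomputed only with each cell left out, and moved by less than that SD. Thinning sets all totals equal. The SD used, the larger of the groups, exceeded each of these differences, so a difference could vanish and still pass. The check therefore does not show that they were stable. Genes with few reads are limited by depth: a count of 0 in the summed libraries still allows 3 reads.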

Other observations

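All tests of explanations in this part were chosen after the results were seen. Below the minimum for a measured gene, more interferon-stimulated genes were read in micronucleated cells only than in the other cells only. Of the 41 listed genes with any read, 18 were read in micronucleated cells only, 3 (Oas3, Usp18 and Sp100) in the other cells only and 20 in both. Random lists matched on expression had a median of 11 genes read in micronucleated cells only (central 95% 6 to 15), so the count lay at percentile 99.8. The reads were thin and scattered: the 18 genes were spread over 14 of 21 cells. Among the better read were Dtx3l, which binds the poly-ADP-ribose polymerase Parp9 (56 reads in 6 cells), and Ifi27l2a (50 reads in 5 cells, 24 of them in cell 10). Others were the GTPase gene Ifi47 (45 reads in 2 cells) and the RNA helicase gene Dhx58 (27 reads, 26 in cell 7). Oasl1, Oas1g, Irf7, Irgm2 and Gbp7 had only 1 read each. Without cell 10, which held most macrophage transcripts, the count was 14 of 37, at percentile 98.8. Without all 4 cells with macrophage markers it was 10 of 33, at percentile 95.1 and inside the central 95% of random lists (3 to 11). More cells were micronucleated (21 against 14), which the random lists share.

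Markers of other tissues were scarce apart from neural markers and a few chondrocyte genes. Neural markers stood at 153.9 CPM in micronucleated and 112.7 CPM in the other cells, mostly Tubb3, Nes and Stmn2. At least 5 reads of 2 or more neural markers were found in 11 micronucleated and 9 other cells. The neural marker Sox2 had at least 5 reads in 8 and 6 cells. Chondrocyte markers stood at 124.9 and 86.8 CPM: the cartilage regulator gene Sox9 had at least 5 reads in 11 of 21 and 9 of 14 cells, and Col2a1 had 854 of its reads in micronucleated cell 13. Skeletal muscle markers were at 3.16 and 10.1 CPM, adipocyte at 3.70 and 7.58, epithelial at 0.541 and 2.41, endothelial at 0.361 and 0.775 and erythroid at 0.271 and 0.345. Macrophage markers were at 896.8 and 18.7 CPM. Of the sex-linked genes Xist, which silences an X chromosome, had at least 5 reads in 8 and 4 cells, and Kdm5d of the Y chromosome had 17 reads in 1 cell without micronuclei.

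The higher interferon-stimulated list in summed counts (median log2 ratio 0.96) was weighed against 2 technical explanations. For the measured genes, cells with macrophage transcripts are argued against as the whole cause. Without the 4 such cells the median was 1.28, over the 10 genes then measured. This does not cover listed genes below the minimum. Their count read in micronucleated cells only moved to percentile 95.1 without these cells, as given above. A few deep cells may set the summed ratio: with equal weight for every cell the median was 0.030. The median of 1.00 after thinning also weighs the cells equally, but rests on the 7 genes then measured. With equal weight in the same 30 cells, not thinned, all 11 genes gave 0.19. Gene set and depth both differ between these values, so they do not decide whether deep cells set the ratio. A higher interferon-stimulated level in micronucleated cells as such was not decided, since the equal-weight median lay at percentile 37.7 of random lists, and it stays open.

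The leading genes were picked among 4167 genes past the minimums of CPM and cells, so extremes are found without any difference. The 12 lower genes went no further than this explanation gives. In 20 of 20 simulated sets with no gene changed the twelfth gene was at least as far from 0 as the real twelfth, at −1.55. The simulated median was −1.82, so the ratios of the lower genes alone are no evidence of a difference. For the 12 higher genes 0 of the 20 simulated sets reached the real twelfth gene, at 2.31, against a highest simulated value of 2.18. The simulated leading gene, however, reached 4.40, above the smallest ratio of Sharpin (4.14), and a simulation rests on assumed variation, so chance extremes may account for them. The larger number of genes detected in micronucleated cells stays open too: the median of 2.31 among cells with 5000 to 8000 genes after thinning decides nothing, since the genes were picked in these same cells, and a difference that goes with micronuclei was not tested.

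Macrophage transcripts in micronucleated cell 10 fit material of a macrophage captured beside a fibroblast: 8 of 8 markers had at least 5 reads, with Lyz2 at 13945.8 CPM. A macrophage alone is argued against, because the extracellular matrix list reached 18672 CPM in this cell, above the 25th percentile of the other cells (15123 CPM) and above 13 of 34 of them. Carry-over from another of the 35 libraries is argued against, because the next highest held 3.37% as many marker reads. Carry-over from libraries not used here, and debris of a macrophage taken up by the fibroblast, could not be tested. No biological explanation was tested for this cell, as the design names none.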
